A study of Danio rerio with 2 samples.

How the data were processed

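Libraries were made with the TruSeq RNA kit from head tissue of AB zebrafish embryos at 33 hours post fertilisation and read as 100 bp pairs on a HiSeq 2000, per the labels' protocols. Per the submitters' processing notes the tools were bcl2fastq 2.17.1.14, cutadapt, HISAT2 2.0.1, HTSeq 0.6.1 and DESeq2, with genome build GRCz11. The role of each tool, the annotation release and the strand setting are not given in the sources used here. Without a known strand setting, reads of overlapping and antisense genes cannot be told apart, and genes with near-identical copies (crygm2d crystallins, globins, hsp70 genes) have uncertain single values. The labels' protocol speaks of several independent samples, and 2 libraries, 1 wildtype and 1 rbm24a mutant, were analysed here.

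The deposited table of all features gives a whole-number read count per feature and library, without normalisation, for 51544 features: 31571 annotated genes and 19973 features without an Ensembl gene. The authors also gave RPKM values in that table, which are per kilobase and scaled by the summed counts of the library. The length column of the deposited table is in base pairs and looks like the genomic span of a gene. The authors' deposited table of their comparison gives counts and FPKM values equal to those of the other table, normalised counts (a signal scaled by size factors), a fold or ratio, its log2, and a p-value and adjusted p-value. There the authors' fold and log2 fold are wildtype over mutant, and the p-values are the authors' own and were not recomputed. No column of per-sample values from other samples was present (0 columns).

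Counts were scaled to CPM by the library total of all features. The design fixed before the data were examined assumed RPKM values. Because the table also holds counts, the same rules with the same numbers were applied to CPM, as that design stated for this case, and RPKM was added as an alternative. The ratio was log2((mutant CPM + 1)/(wildtype CPM + 1)) for features with a mean of at least 1 CPM, and higher or lower means a log2 ratio of at least 1 or at most -1. This scale understates the difference of features with low counts, so folds printed for single genes are ratios of CPM without a pseudocount. Their 95% Clopper-Pearson intervals cover counting error only, since 1 library per group gives no variation between samples. PCR reads are not independent molecules, so the intervals may be too narrow even for counting error. A count of 0 was set to a floor of 3 counts per library, 0.212 CPM in the wildtype and 0.180 CPM in the mutant library, to give an approximate lower bound of the fold. The exact interval can reach below that bound, so its lower limit is printed beside it. With 1 library per group no p-value was computed.

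Gene lists (29, with 883 symbols) were fixed before the data were examined. Of these symbols 627 matched exactly, 23 after ignoring case and 166 after removing a final a or b, and 67 did not match. Each list's median was set against 10000 random lists matched on 20 bins of mean CPM, as a percentile that describes these libraries. The names table gave a symbol for 26147 of the 31571 annotated genes, many as the mammalian name. Both RBM24 entries of that table were told apart by their span: 35150 bp in the file against 35948 bp for rbm24a in the RefSeq table of assembly GRCz12tu. Of the rows within 10 places, 7 neighbours were shared with rbm24a of the RefSeq table and 0 with rbm24b. Chromosomes and distances came from that table by unique symbol for 16409 features, and its coordinates are not printed because the build differs from GRCz11.

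Named genes followed a rule fixed before the data were examined: rbm24a and rbm24b; the 12 highest and 12 lowest log2 ratios with a proper symbol; up to 4 members of each list with the largest absolute ratio, and the 4 crystallins with the highest mean; the 10 largest and 10 smallest folds of mutant over wildtype in the authors' table with a proper symbol, where 3 genes with such a symbol were higher in the mutant library; and up to 6 genes within 10 Mb of rbm24a past 2-fold. Symbols starting with AC and a digit, zmp or linc were also treated as clone or placeholder names, although the rule did not spell them out; otherwise AC024175.4 and a linc gene (ENSDARG00000094560, log2 ratio 2.67) would have been named by it. Others are marked in the text as named after their values were seen.

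The steps were tested on simulated data for the mutant against wildtype comparison, with 200 of 18096 genes given known folds. The 2-fold rule recovered 58 of 66 genes with a true log2 fold of 1.5, 65 of 67 with 2 and 67 of 67 with 3, and called 1 of 17896 unchanged genes. Intervals held the true ratio for 95.1% of 2000 unchanged genes, and 6 of 100 unchanged lists of random genes lay outside the random range. The simulated counts varied by counting error alone. These rates therefore leave out variation between samples and are not error rates of the comparison of 1 library with 1. Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, rescaling to a median log2 ratio of 0, TPM, no filter, a mean of at least 5, a 4-fold threshold, unmatched random lists, crystallins with a mean of at least 10, 1.5-fold or 5 Mb around rbm24a, and stricter thresholds in the authors' table. Deposited RPKM values, the authors' size factors and annotated genes alone were added after seeing the data. A list of cholesterol synthesis genes was also added after seeing the data, and some genes are not reported here and were left out of it. Software was Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.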

Results

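Messenger RNA was measured in head tissue of zebrafish embryos of the AB strain at 33 hours post fertilisation. The head was cut off in front of the otic vesicle, the rudiment of the inner ear. 1 library came from wildtype embryos and 1 from embryos of an rbm24a mutant line carrying an 8 bp TALEN deletion in the first exon. Rbm24a is an RNA-binding protein, and the series title places the work around translation, crystallin accumulation and lens transparency. The deposited table assigned 14148577 reads to features in the wildtype library and 16667612 in the mutant library. Each group had 1 library, so no difference below has a replicate check. Intervals are 95% exact intervals that cover counting error only, except where a range from redrawn counts is named.

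The targeted gene was compared first, as a check of the labels. rbm24a (ENSDARG00000102995) had 224 reads in the wildtype library and 121 in the mutant library, or 15.8 and 7.26 CPM, counts scaled to a common library total. This was 2.18-fold lower in the mutant library (interval 1.74 to 2.74), a log2 ratio of -1.03 with a pseudocount of 1 CPM. Its paralog rbm24b had 31 and 13 reads, 2.81-fold lower in the mutant library (interval 1.43 to 5.85) and a log2 ratio of -0.84. An 8 bp deletion need not remove a transcript, so these levels do not measure the loss of the protein.

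The series title asks about crystallins, the structural proteins of the lens, and their transcripts were lower as a group in the mutant library. Of 32 measured crystallin genes, 26 were lower by at least 2-fold, 1 was higher and 5 lay within 2-fold. Of the 32, 18 lie outside the crygm2d cluster, whose near-identical copies may share reads, so the members are not independent. The median log2 ratio was -1.90, a percentile of 0 among 10000 random lists of the same size and expression, whose medians lay between -0.12 and 0.11. Summed over the list, crystallin transcripts had 2762 CPM in the wildtype library and 644.0 CPM in the mutant library, a 4.29-fold difference.

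The beta-crystallin genes crybb1l1 (ENSDARG00000007576) and crybb1 (ENSDARG00000068507) had the lowest ratios. crybb1l1 had 273 CPM in the wildtype library and 11.9 CPM in the mutant library, 23.0-fold lower (interval 19.9 to 26.6). For crybb1 the levels were 339 and 22.6 CPM, 15.0-fold lower (interval 13.5 to 16.7). cryba1b was 8.70-fold lower (interval 7.91 to 9.59), and crybb1l2, among the 4 crystallins with the highest mean, 3.68-fold lower (interval 3.46 to 3.91). crygm2d2 had 264 wildtype and 22 mutant reads, but the crygm2d genes are near-identical copies whose reads may be split between them, so their single values are uncertain. The ratios were uneven: crygm2d4 and crygm2d17 had log2 ratios of -0.23 and -0.27, CRYAB 0.01 and crybg1a 0.31. crybg1b was the member higher in the mutant library, with 145 against 52 reads. These last 5 genes were named after their values were seen. The lens was not measured apart from the rest of the head, so values of list members need not come from the lens.

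**Figure D1:**
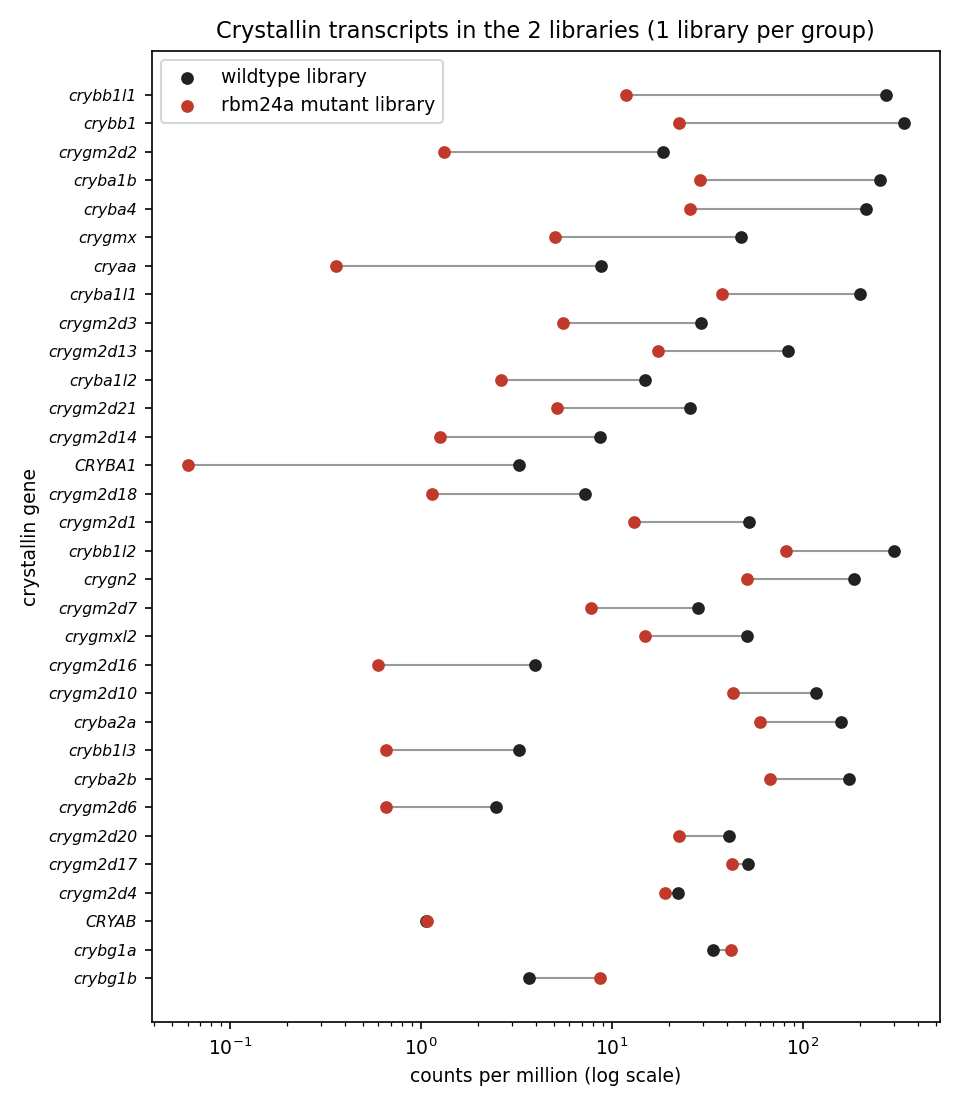
CPM (log axis) of the 32 measured crystallin genes in the wildtype (black) and rbm24a mutant (red) library, 1 library per group, ordered by log2 ratio. Most red points lie left of the black ones, from crybb1l1 at the top (273 and 11.9 CPM) to crybg1b at the bottom, which was higher in the mutant library.

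Other structural genes of lens fibre cells were lower too. Of 17 measured members, 11 were lower by at least 2-fold, none was higher, and the median log2 ratio was -1.45 (percentile 0). It was -0.70 with a pseudocount of 5 and -2.13 with a mean of at least 5 CPM. mipb, a water channel of the lens fibre membrane, was 15.4-fold lower (interval 13.0 to 18.4). The beaded filament genes bfsp1 and bfsp2 were 9.81-fold (interval 7.35 to 13.4) and 15.8-fold lower (interval 8.80 to 31.2). An LCTL gene had 112 reads in the wildtype library and 0 in the mutant library. This was 44.0-fold lower against a floor of 3 counts per library (lower limit of the interval 35.2). The list of lens transcription factors did not share this in head tissue: of 18 measured, 17 lay within 2-fold. Its median log2 ratio was 0.09 (percentile 88.2). The exception was hsf4, a heat shock family factor of the lens, with 29 and 4 reads (8.54-fold lower, interval 2.999 to 33.4), and PROX1 had a log2 ratio of -0.59. Expression of these factors in the lens was not measured apart from the rest of the head, so their lens levels are not known.

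Transcripts of red blood cells were also lower in the mutant library. Of 19 measured genes of erythrocytes and haem synthesis, 15 were lower by at least 2-fold, none was higher, and the median log2 ratio was -1.96 (percentile 0). The list summed to 1438 CPM in the wildtype library and 287 CPM in the mutant library. hbae3, an embryonic alpha globin, had 546 and 84.2 CPM (6.48-fold lower, interval 6.12 to 6.87), and hbae1.1 and hbae1.3 had log2 ratios of -4.01 and -3.92. The globin copies resemble each other, so values of single globins are uncertain. slc4a1a, the anion exchanger of the red cell membrane, was 8.21-fold lower (interval 7.09 to 9.56).

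Several heart transcripts at low levels were higher in the mutant library. Of 8 measured members, 5 were higher by at least 2-fold and none was lower, with a median log2 ratio of 1.83 (percentile 100), or 2.14 with the genes at 0 counts set at their bound. This median rests on low counts: it was 0.55 without a filter on low values, 0.60 with a pseudocount of 5, 3.32 with a pseudocount of 0.1 and 1.06 with deposited RPKM values. With a mean of at least 5 CPM it was 0.10, over too few members for a percentile. hand2 had 119 reads in the mutant library and 7 in the wildtype library (14.4-fold higher, interval 6.79 to 36.7). This gene is also in the cartilage and cranial neural crest list, so it is not particular to the heart list. MYH6 had 101 and 8 reads (10.7-fold higher, interval 5.24 to 25.5) and myh7 80 and 5. myl7, a myosin light chain of heart muscle, had 51 reads in the mutant library and 0 in the wildtype library. This was 14.4-fold higher against the floor of 3 counts per library (lower limit of the interval 11.3). The whole list summed to 48.7 CPM in the mutant library and 23.3 CPM in the wildtype library. Skeletal muscle genes had a median of 0.04 (percentile 57.9), with 4 of 7 members above 0 and 3 below. By at least 2-fold, 2 were higher and none was lower. These were pvalb2 at 50 mutant and 2 wildtype reads (21.2-fold higher, interval 5.58 to 180) and an ACTA1 gene at 75 and 22 (2.89-fold higher, interval 1.78 to 4.89). Another ACTA1 gene had a log2 ratio of 0.81 and myod1 -0.59. Genes of the sarcomere of all striated muscle had a median of -0.30 (percentile 5.80), with 6 of 8 members below 0. tmod4, ldb3a and nexn had log2 ratios of -0.77, -0.76 and -0.66, and MYOM2 was 4.17-fold higher (interval 2.22 to 8.53).

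Across all features, 18094 had a mean of at least 1 CPM, and 94.95% of them lay within 2-fold between the libraries. In the mutant library 402 features were higher and 511 lower by at least 2-fold. Redrawing the reads of each feature at the shared rate gave at most 2 features higher and 2 lower in any of 100 draws. Features that the table does not tie to an annotated gene passed 2-fold more often (13.0% of 1822) than annotated genes (4.15% of 16272). Over the alternative pseudocounts and filters the numbers at 2-fold ranged from 97 to 672 higher and from 164 to 830 lower, and TPM values gave 812 higher and 1381 lower.

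The 12 named genes with the lowest ratios included 4 lens genes of the lists (crybb1l1, crybb1, mipb and LCTL) and 3 globins (HBE1, hbae1.1 and hbae1.3). HBE1 (ENSDARG00000087390), which is outside the erythrocyte list, had 486 wildtype reads and 1 mutant read, a ratio of 573-fold with an interval of 102 to 22660. CAPN3, a calpain protease, was 30.4-fold lower (interval 21.2 to 45.0), and dnph1 and tdh2 had log2 ratios of -3.45 and -3.34. The heat shock genes hsp70.3 and HSPA2 had log2 ratios of -4.29 and -3.53, and hsp70 genes have near-identical copies, so both are uncertain. HSPA2 is not in the list of heat shock and chaperone genes fixed beforehand, of which 21 were measured. Of these, 3 were lower by at least 2-fold and the median was -0.28 (percentile 0.01). Beside hsp70.3 these were hsp70l (20.4-fold lower, interval 10.8 to 43.3) and hsp90aa1.2 (7.85-fold lower, interval 7.08 to 8.73), a chaperone gene.

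The 12 named genes with the highest ratios were ptpdc1b, f10, ANXA3, LGALS8, cyp2aa7, OSCP1, GGACT, fkbp15a, btr04, hand2, MCHR1 and tgm1l2. ptpdc1b had 604 mutant and 17 wildtype reads (30.2-fold higher, interval 18.7 to 52.1). f10, which encodes coagulation factor X, had 212 and 3 reads (59.99-fold higher, interval 20.2 to 293). The annexin gene ANXA3 was 12.2-fold higher (interval 8.76 to 17.4), and LGALS8, a galectin gene, 19.3-fold higher (interval 9.14 to 48.7). OSCP1 and GGACT each had 94 mutant reads and 0 wildtype reads, 26.6-fold higher against the floor of 3 counts per library (lower limit of the interval 21.2). MCHR1 had 72 and 0, 20.4-fold higher against the same floor (lower limit 16.1).

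**Figure D2:**
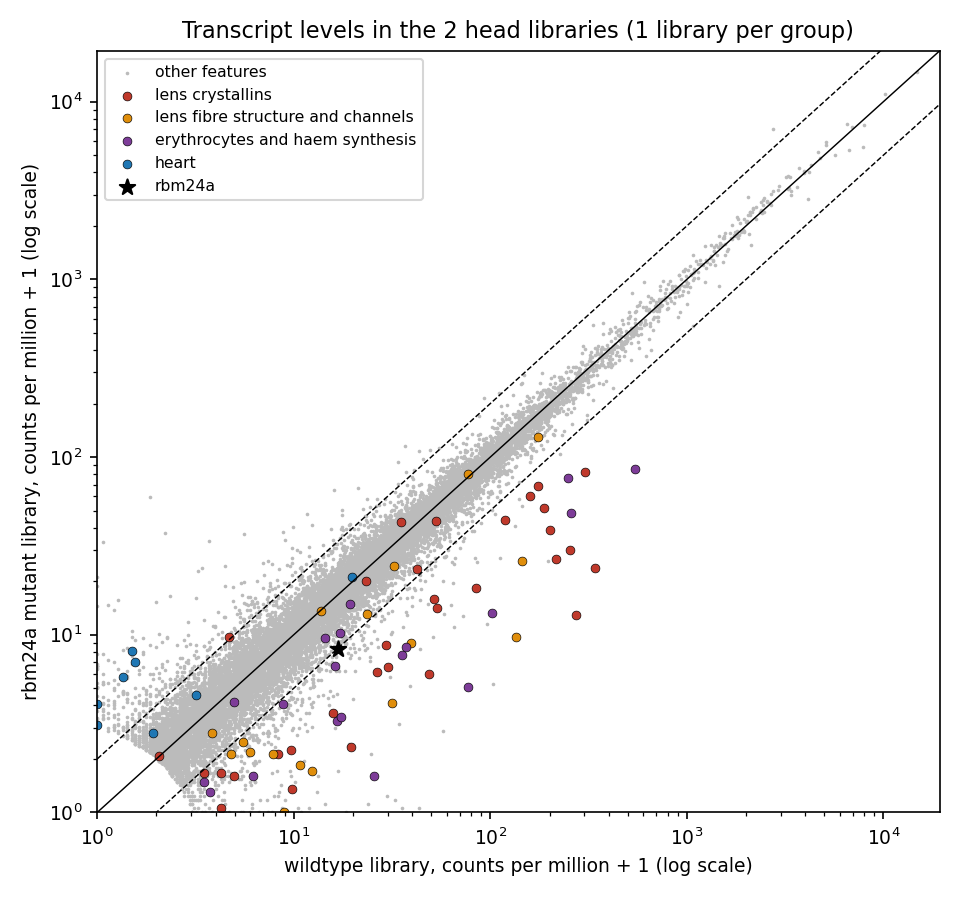
CPM plus 1 in the wildtype library (horizontal, log axis) and in the rbm24a mutant library (vertical, log axis) for features with a mean of at least 1 CPM, 1 library per group, with the solid line at equal levels and the dashed lines at 2-fold. Crystallins, lens fibre genes and erythrocyte genes lie mostly below the lower dashed line, 5 heart genes lie above the upper one, and 94.95% of features lie within 2-fold.

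The eye was not measured apart from the rest of the head, so the values of retinal and pigment genes are those of head tissue. Genes of retinal progenitors and neurons were slightly lower in the mutant library. Their median log2 ratio was -0.32 over 20 genes (percentile 0.01). atoh7, needed for retinal ganglion cells, was the member past 2-fold, with 495 wildtype and 167 mutant reads (3.49-fold lower, interval 2.92 to 4.19). crx and vsx1 had log2 ratios of -0.80 and -0.79. Pigment genes had a median of 0.10 (percentile 95.1), with RPE65, the isomerase of the visual cycle, 2.91-fold higher (interval 1.77 to 4.98) and the melanosome gene pmela at a log2 ratio of 0.69.

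Brain region genes had a median log2 ratio of 0.27 (percentile 99.99), with none of 22 past 2-fold and FGF8, DLX5 and DLX1 at 0.74, 0.69 and 0.68. IRX1 was at -0.52, and 4 of the 22 lay below 0. Epidermis and ionocyte genes had a median of 0.22 (percentile 99.99), with anxa1a 2.35-fold higher (interval 2.203 to 2.504) and cyt1 at -0.74. Endothelial genes also had a median of 0.22 (percentile 99.1), but CLDN5 was at -0.95, the summed reads gave -0.33, and the percentile was 91.7 with deposited RPKM values. Cytosolic ribosomal protein genes had a median of 0.11 (percentile 100), with none of 79 past 2-fold. Of these, 63 lay above 0 and 16 below, and the largest absolute ratios were lower, with rps27.1 at -0.66 and rpl6 at -0.45. Medians lay below the random range for hypoxia and glycolysis genes (-0.16, percentile 0.38) and for Rbm and splicing regulators (-0.15, percentile 0.63). In the former, TPI1 was 2.19-fold lower (interval 1.99 to 2.42). egln3 had a log2 ratio of 0.83, and 15 of 37 members lay above 0. In the latter, mbnl1 and srrm3, both regulators of splicing, were 3.37-fold (interval 2.36 to 4.89) and 3.18-fold lower (interval 2.33 to 4.39). There esrp1 had a log2 ratio of 0.75, and 10 of 29 members lay above 0.

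**Figure D3:**
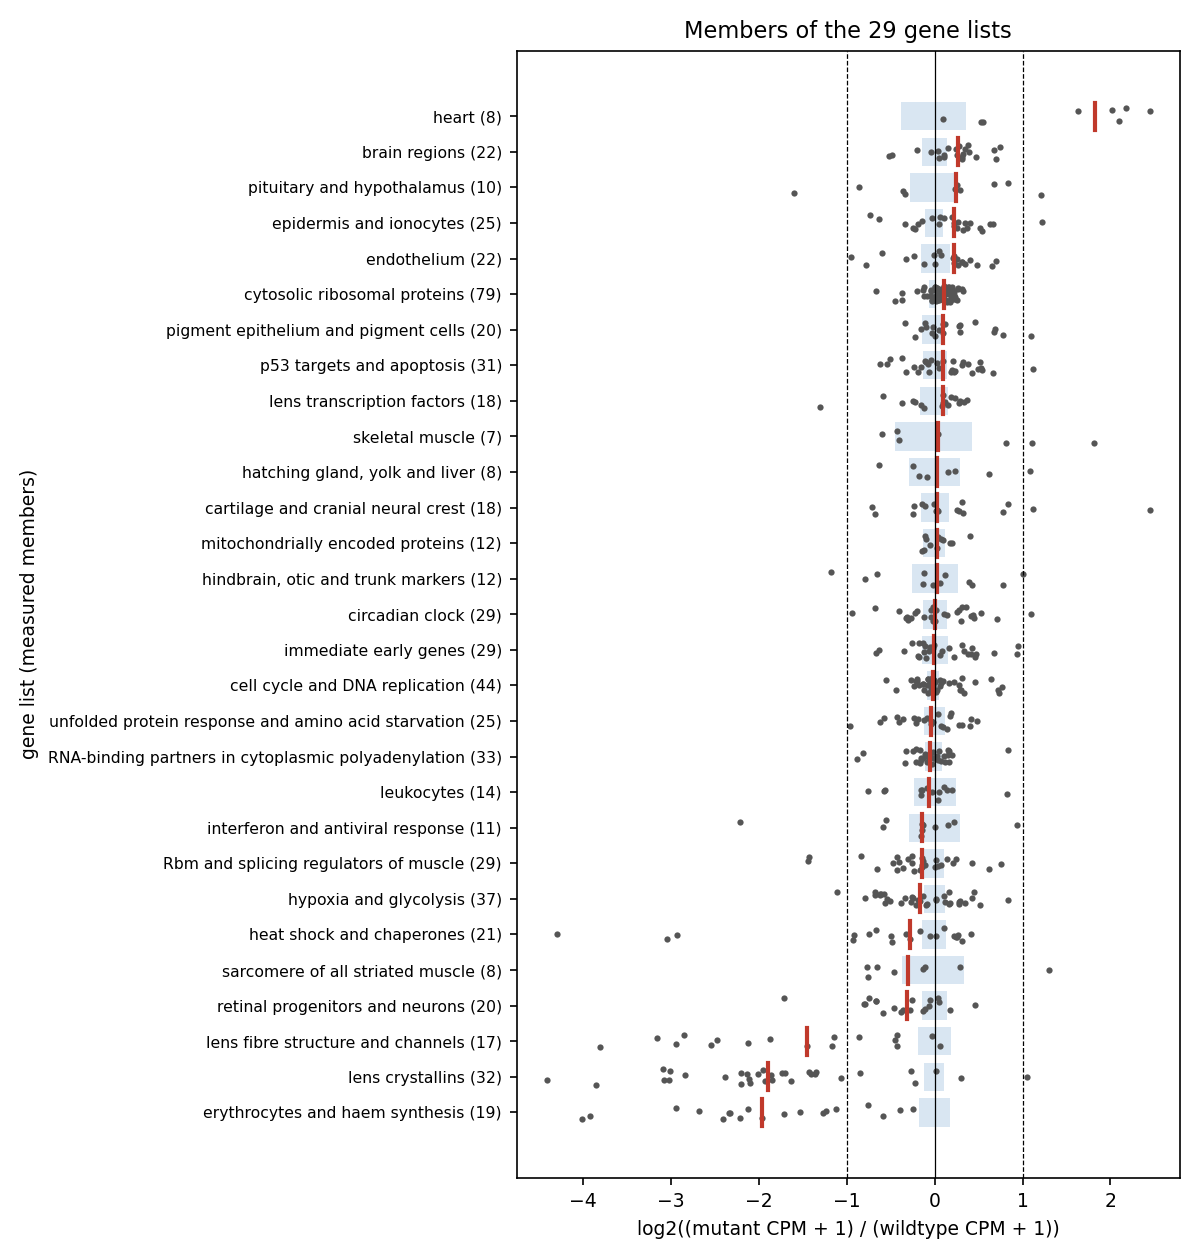
Log2 ratio of mutant over wildtype CPM with a pseudocount of 1 (horizontal) for each measured member (grey points) of the 29 gene lists, with the number measured in parentheses. Red bars mark list medians and pale blue bands hold 95% of the medians of random lists, and 12 medians lie outside their band, among them erythrocytes (-1.96), lens crystallins (-1.90) and heart (1.83).

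The remaining lists had medians inside their random range, and 3 of them left it under an alternative. For hindbrain, otic and trunk markers the median was 0.02 (percentile 54.05), with the otic gene stm at -1.18 and oc90 at 1.00. It was 0.03 for cartilage and cranial neural crest (percentile 64.9), with hand2 at 2.45, barx1 at 1.12 and 7 of 18 members below 0. For hatching gland, yolk and liver it was 0.03 (percentile 62.5; rbp4 1.09). For leukocytes it was -0.06 (percentile 28.5), with MFAP4 at 0.82 and lyz at -0.76. Pituitary and hypothalamus genes were at 0.24 (percentile 97.2, but 97.61 with RPKM and 97.93 with a pseudocount of 5), with TSHB at -1.60 and smtla at 1.21. Stress lists lay at 0.10 for p53 targets and apoptosis (percentile 92.5, but 99.69 without a filter; pmaip1 1.12), -0.04 for the unfolded protein response and amino acid starvation (percentile 28.3; DNAJB9 -0.97), and -0.01 for immediate early genes (percentile 44.6, but 98.4 with RPKM; klf2b 0.95). Circadian clock genes had a median of 0.01 (percentile 53.4; per3 1.09), and interferon and antiviral genes -0.14 (percentile 16.7; eif2ak2 -2.22). Partners in cytoplasmic polyadenylation, a process that sets translation, had a median of -0.06 over 33 genes, none past 2-fold (percentile 16.25; pabpc4 -0.89). Mitochondrially encoded protein genes were at 0.03 (percentile 79.5) and cell cycle and DNA replication genes at -0.02 (percentile 47.5; cenpf 0.77). In all 12 of 29 lists lay outside the random range. Of lists of unrelated genes 1.45 would, but members of these lists share cell types or pathways and some genes are in more than 1 list, so that number is not a chance level for them.

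The authors' deposited table of their own comparison lists 37 genes, of which 33 were lower and 4 higher in the mutant library. Its fold changes are written as wildtype over mutant, since they equal the wildtype over the mutant normalised count in that table. Of the 33, 12 belong to the crystallin list, 5 to the erythrocyte list, 2 to the lens fibre list and 2 to the heat shock list. In the authors' deposited table crybb1l1 has a fold of 22.5, crybb1 a fold of 14.7, mipb 15.1 and atoh7 3.41. That comparison sets 1 library against 1, so its p-values rest on no measured spread between samples and are not printed. The genes higher in the mutant library in the authors' deposited table are anxa1a (2.402-fold), dbi (2.11-fold), hmgn3 (2.01-fold) and AC024175.4 (2.63-fold), the last a clone name outside the rule for named genes, named after its values were seen. AC024175.4 held 0.701% of all mutant reads and 0.273% of wildtype reads. The kind of RNA it stands for was not checked, so this is not read as a raised protein-coding gene. The authors' deposited table holds no gene below an FPKM of 21.6 in the wildtype library, and 865 features past 2-fold by CPM lay below that level.

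Animals selected for a mutation also share the chromosome segment around it, so the neighbours of rbm24a were compared with other genes. Of 108 measured genes placed within 10 Mb of rbm24a, 1 differed by at least 2-fold, which is 0.926% (exact interval 0.0234% to 5.05%). It was tfpi2, with 144 wildtype and 71 mutant reads (2.39-fold lower, interval 1.79 to 3.22). On the whole chromosome 9 of 467 genes differed by 2-fold (1.93%, interval 0.885% to 3.63%), and on the other chromosomes 404 of 10975 (3.68%, interval 3.34% to 4.05%).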

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

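No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out and no other split of the samples exists. Alternatives with deposited RPKM values, the authors' size factors and annotated genes alone were chosen after seeing the data. No feature named as past 2-fold and no list outside its random range turned its direction under any alternative run. The count of features depends on the settings: against 402 higher and 511 lower, a pseudocount of 0.1 gave 672 and 830, a pseudocount of 5 gave 97 and 164, TPM gave 812 and 1381, a mean of at least 5 gave 171 and 243, the 4-fold threshold gave 75 and 100, and RPKM gave 205 and 279. A higher mean or threshold leaves fewer features by construction. So does a larger pseudocount, which pulls ratios toward 0. For TPM and RPKM the cause was not tested. The median of the lens crystallins, -1.90 (counting interval -1.96 to -1.79), was -2.20 with a pseudocount of 0.1 and -1.37 with 5, again the pull of the pseudocount. It was -1.70 without a filter and -1.74 with RPKM, and for these the cause was not tested. The rbm24a log2 ratio of -1.03 was -0.76 with a pseudocount of 5, which pulls ratios of low values toward 0. Within 10 Mb of rbm24a 10.19% of genes passed 1.5-fold, against 12.22% on the other chromosomes, and within 5 Mb 0 of 83 passed 2-fold (0%). The rescaling divided mutant values by a factor whose log2 was 0.00053. Lists outside their random range numbered 10 to 13 over the alternatives, and the endothelium list stayed outside it in 4 of 7. Inside it with the main settings, the pituitary and hypothalamus list stayed inside in 5 of 7, and the p53 and immediate early lists in 6 of 7 each. Of 203 list medians under alternatives 179 stayed within counting error, taken from the same kind of redraws, and 24 moved. Of 685 ratios of named genes 538 stayed within the counting interval, taken with the pseudocount of 1, and 147 moved. Depth limits low genes: 3 counts are worth 0.212 CPM in the wildtype and 0.180 CPM in the mutant library.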

Other observations

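All tests in this part were chosen after the results were seen. Many genes of cholesterol synthesis, a group that no list fixed beforehand covered, were higher in the mutant library. CYP51A1, a demethylase of the pathway, had 36.7 against 7.85 CPM (4.67-fold higher, interval 3.81 to 5.77). Of 23 measured members 11 were higher by at least 2-fold, none was lower by 2-fold, and 22 lay above 0. fdps had 108 against 42.5 CPM (2.53-fold higher, interval 2.31 to 2.78), SQLE was 2.96-fold higher (interval 2.42 to 3.65), and srebf2, the transcription factor of the pathway, 2.25-fold higher (interval 2.06 to 2.46). idi1 lay at a log2 ratio of 0.05 and lbr at -0.03. Without CYP51A1, the median log2 ratio of the other 22 genes was 0.91, against a random range of -0.15 to 0.17. The list was written after high values in this pathway had been seen and is not complete, so this does not test whether the pathway as a whole is higher, which stays a hypothesis. This describes a pair of libraries, and clutch, stage and genotype cannot be separated with 1 library per group.

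Crystallin and lens fibre transcripts were lower in the mutant library, with 37 of 49 measured members of these lists lower by at least 2-fold. The crygm2d copies, which may share reads, are counted singly in this. Counting error alone gave 0 such lower members in any of 100 draws. In the same head tissue 17 of 18 lens transcription factors lay within 2-fold, but their levels in the lens itself were not measured. An equal loss of all lens fibre transcripts, as from fewer fibre cells in the sample, stays open. The ratios were uneven, and for 3 of 18 crystallins outside the crygm2d cluster the interval held the summed log2 ratio of -2.29, with 7 intervals wholly below it and 8 wholly above. These intervals leave out variation between samples, and expression outside the lens, which would raise members and the sum with them, was not tested. A younger mutant sample stays open as well, since the pigment list (percentile 95.1) has members on both sides of 0, and an effect of the rbm24a mutation was not tested against clutch differences.

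Red cell transcripts were lower too. Reads moved between globin copies are argued against by the summed counts of the 6 measured globins of the list, with a log2 ratio of -2.45 (interval -2.50 to -2.39, 5.45-fold lower), and of all 15 globin entries of the table at any level, HBE1 among them, with -2.48 (interval -2.54 to -2.43), and 9 of the 13 other list members were lower by 2-fold. Fewer red cells caught with the cut head may account for an equal loss, and this cannot be told apart from a loss in the embryo: 1 of the 13, slc4a1a, lay below the summed globin ratio by more than its interval and 6 lay above it, which expression in other cells could give. Several heart genes were higher in the same library, but hindbrain, otic and trunk markers, listed to follow the position of the cut, had a median log2 ratio of 0.02 (percentile 54.05) with 6 of 12 members above 0 and 6 below, so these values do not decide whether the cut differed.

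Some genes were nearly absent from 1 library, with 3 counts or fewer: 55 in the mutant library and 63 in the wildtype library. Outside the lens, erythrocyte, heat shock and heart lists there were 114, of which 51 were features without an annotated gene. Inherited sequence differences between the animals sampled may contribute. Neighbours were taken in the table's order among features with a mean of at least 1 CPM, so features below that level can lie between them. In this order 9 pairs were neighbours, all near absent in the same library. In 1000 random draws matched on level and annotation the mean was 1.39 and the most 7. Pieces of 1 transcript counted as separate features, or tandem copies, could give the same and stay open. A segment carried with the rbm24a mutation cannot be told apart from chance, since 0 of 110 genes within 10 Mb were near absent (exact upper limit 3.30%) against 0.237% elsewhere.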
